A study of Homo sapiens with 4 samples.

How the data were processed

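In situ Hi-C of MCF-7 cells was made with the restriction enzyme MboI and biotin fill-in, per the labels' protocols, from 4 libraries. The labels assign 2 biological replicates to ICI 182,780 and 2 to estrogen. They give the length of the estrogen treatment without a unit, so it is not printed. The submitters' processing notes name bcl2fastq 2.17.1.14, Bowtie2 2.3.0 and build hg18. The tool that called the boundaries, its resolution settings and its threshold are not given in the sources used here. The authors deposited 1 list of boundary positions per condition, which the labels name for both replicates. Per the file headers, each list is on hg18, belongs to the ICI or the E2 condition and was made from 4 numbered inputs, and the cells are called a clone, a word that the sample labels do not use. What the 4 inputs are is not explained; they were read as pooled runs of the 2 replicates. Every window was 20 kb wide and began on a multiple of 20 kb, which was checked on each line. The lists hold no score, count or coverage. Other processed tracks that the labels name were not analysed here.

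Except where stated, the comparisons, gene lists and alternatives were fixed before the data were examined, for domain intervals or boundaries of unknown form. Because the lists turned out to hold boundary windows of a single width, boundaries were matched by their midpoints, as planned for that case. A boundary was called shared where the other list had a boundary within 40 kb, and ICI-only or E2-only otherwise. The planned comparison of domains by reciprocal overlap was made on the segments between neighbouring midpoints, a choice made after the form of the lists was seen. A segment was stable at a reciprocal overlap of at least 0.75. A segment that was not stable was divided where 2 or more segments of the other list lay at least 0.75 inside it and covered at least 0.75 of it, and an E2 segment joined ICI segments where the same held in the other direction. A segment that was neither stable nor divided was counted as lying with others inside 1 segment of the other list where that segment, stable or not, met the rule for 2 or more segments inside it. The planned comparison of caller scores was not made, since the lists hold none. The planned test of 6 fixed gene lists was not made either, because the only gene table used here is on GRCh38 and positions are not carried between builds. Genes are therefore named only by the chromosome that carries them, as background.

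The agreement of the lists was set against 1000 random rotations of 1 list within each chromosome, which keep the order and spacing of its boundaries, and against random positions at least 80 kb apart. Intervals on list totals, medians and genome-wide boundary shares come from 10000 bootstrap resamples of whole chromosomes and cover the spread between chromosomes only. Shares on 1 chromosome, of segments and of counts carry exact binomial (Clopper-Pearson) intervals at 95%, which cover counting error only. They treat the members as independent. Neighbouring segments share a boundary and can change together, so the intervals for segments are likely too narrow. Chromosomes were compared with Fisher's exact test and Benjamini-Hochberg adjustment, and with 10000 shuffles. The boundaries and segments named in the text are, per condition, the 5 boundaries farthest from any boundary of the other list (inside its span), the 5 longest ICI segments that were divided and the 5 longest E2 segments that joined ICI segments (stable segments left out), plus the genes TFF1, GREB1, FOXC1, NRIP1 and PGR. ESR1 and CCND1, members of the fixed lists, were added beside them. Chromosomes 3, 9, 10, 14, 17, 20 and X were singled out after their values were seen. Window coordinates are 1-based on hg18, and positions in Mb are window midpoints unless called starts.

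The matching was tested on simulated data made from the 4955 ICI boundaries, with boundaries removed, added and displaced by up to 1 window. In 20 runs the number found was a median of 100% of the number removed, and likewise 100% of the number added. This outcome was fixed in advance, since displacements stayed inside the 40 kb tolerance and added boundaries were kept beyond it. It checks the counting only, and displacements near the tolerance were not simulated. Of 40 rotated E2 lists, each compared with further rotations of itself, 2 gave a rotation p below 0.05, a share near the threshold by construction. For the 5 segments of a made-up chromosome the class totals were as built, and only totals were checked. It held only stable segments, divided ones and ones lying with others inside 1 segment. The work used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. Alternatives covered the tolerance, the overlap, the random placement, the sex chromosome, short and long spacings and each chromosome left out. Those for the shared percentage of segments, the autosome minus X difference and the share of ICI-only boundaries near an E2-only boundary were not planned. Leaving out the borders of long stretches without a boundary was not planned either.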

Results

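In situ Hi-C, a proximity ligation assay that reads which parts of the genome lie close together in the nucleus, was carried out on MCF-7 cells. MCF-7 is an established human breast cancer line that carries estrogen receptor alpha. The series holds 4 libraries in 2 conditions, with 2 biological replicates in each. Control cells received ICI 182,780 (fulvestrant), an antagonist of that receptor, and treated cells received estrogen (E2). The comparison addresses how the folded genome of these cells differs between antagonist-treated and estrogen-treated cells. None of the 4 libraries is from untreated cells, so a difference could come from either compound. The measurement analysed here is the position of boundaries between topologically associating domains (TADs), the stretches of chromatin that contact themselves more than their neighbours. Such boundaries are often occupied by the insulator protein CTCF and by cohesin. One list of boundary windows, each 20 kb wide on genome build hg18, stands for both replicates of a condition. The lists hold positions only, so sequencing depth is unknown here, no value has a replicate error, and no test between the conditions is possible. Intervals and p-values below describe the 2 lists, because boundaries and chromosomes are not biological replicates.

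The first comparison asked whether estrogen-treated cells had more or fewer boundaries. The ICI list held 4955 boundaries and the E2 list 4946, on chromosomes 1 to 22 and X. The difference was -9 boundaries (E2 minus ICI), with a 95% bootstrap interval over the 23 chromosomes from -48 to 31. More boundaries were listed in E2 on 7 chromosomes and fewer on 12, and 4 chromosomes had equal numbers. Chromosome 10 had the largest excess in E2, with 231 boundaries against 223. Chromosome 3 had the largest deficit, with 359 against 366. The median distance between neighbouring boundaries was 420 kb in both lists (bootstrap interval 400 to 440 kb in each), with quartiles of 280 and 660 kb in each. The difference of the medians was 0 kb, with an interval from -20 to 20 kb. No pair of neighbours was closer than 80 kb in either list. Neither difference was larger than the spread between chromosomes.

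The second comparison asked how many boundaries kept their place. Of the 4955 ICI boundaries, 4586 (92.6%, bootstrap interval over chromosomes 91.6 to 93.4%) had an E2 boundary within 40 kb. Of the 4946 E2 boundaries, 4586 (92.7%, 91.6 to 93.8%) had an ICI boundary within 40 kb. When the E2 list was rotated around each chromosome 1000 times, a mean of 17.7% of ICI boundaries had a partner, and 22.9% was the highest value. The one-sided rotation p was 0.001, the smallest that this number of rotations can give. This p, like that for segments below, is against random placement only. It does not measure how stable boundaries were under estrogen, for which replicate lists would be needed. Most partners lay in the same window: 3383 ICI boundaries (68.3%) were at an identical position in E2, 958 were displaced by 20 kb and 245 by 40 kb. Beyond the tolerance the numbers fell from 81 at 60 kb to 43 at 80 kb and 30 at 100 kb. Among the 958 boundaries displaced by 1 window, the E2 window lay at the lower coordinate in 506 and at the higher coordinate in 452. The share at the lower coordinate was 52.8% (95% exact binomial interval 49.6 to 56.0%, exact two-sided binomial p = 0.087), so no preferred direction was resolved.

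**Figure D1:**
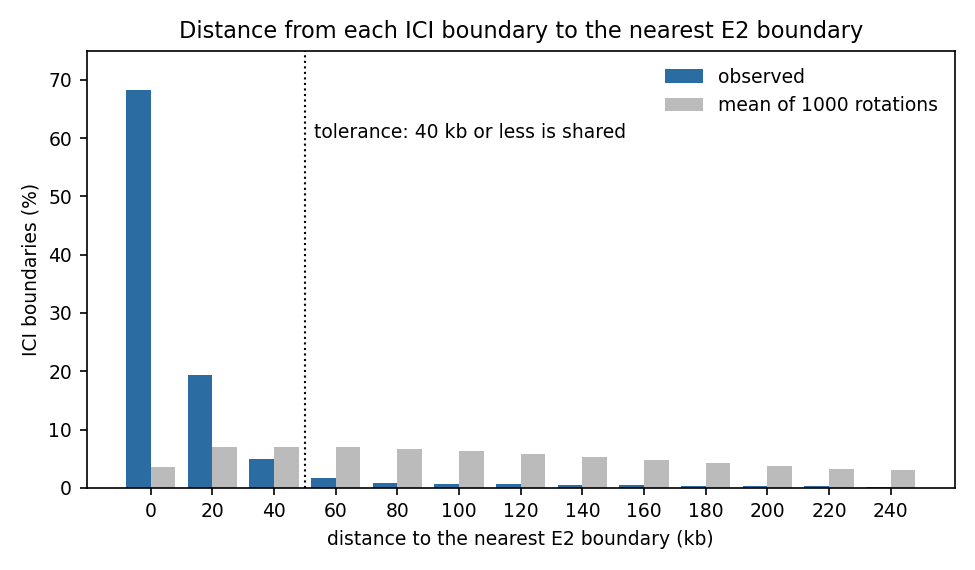
Percentage of the 4955 ICI boundaries (vertical axis) at each distance in kb from the nearest E2 boundary (horizontal axis, shown up to 240 kb), with blue bars for the deposited lists and grey bars for the mean of 1000 rotations of the E2 list. The blue bar at 0 kb reaches 68.3% against 3.53% in the rotations, and from 40 kb on the blue bars lie below the grey ones.

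Some boundaries were found in only 1 list. At the 40 kb tolerance, 369 boundaries were listed only in ICI cells and 360 only in estrogen-treated cells, 729 in all. Since 4586 boundaries of each list were shared, these counts differ by the same 9 as the list totals, and their near equality carries no information beyond those totals. The number of boundaries without a partner depended on the tolerance. With identical positions required it was 1572 in ICI and 1563 in E2, and with 80 kb allowed it was 245 and 236. Whether 369 and 360 exceed the number of differences between replicates of 1 condition cannot be read from lists that hold both replicates together.

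Single boundaries that were far from any boundary of the other list were located by the rule fixed beforehand. The ICI-only boundary farthest from an E2 boundary lay on chromosome 14 at 84680001 to 84700000, 940 kb from its nearest E2 neighbour. It was followed by chromosome 4 at 59980001 to 60000000 (800 kb away), chromosome 5 at 92220001 to 92240000 (720 kb), chromosome 18 at 37200001 to 37220000 (680 kb) and chromosome 2 at 152660001 to 152680000 (640 kb). In each of these 5 places the flanking E2 boundaries were 1.76 to 2.24 Mb apart. The ICI boundary was the only one between them that lay more than 40 kb from both. The E2-only boundary farthest from an ICI boundary lay on chromosome 16 at 17480001 to 17500000, 1980 kb away and inside a 5.56 Mb stretch with no ICI boundary. The next was on chromosome 7 at 65620001 to 65640000, 1640 kb away, inside a 12.4 Mb stretch with no ICI boundary from 54.87 to 67.27 Mb. The remaining E2-only boundaries named by the rule were on chromosome 6 at 78240001 to 78260000 (1420 kb away), chromosome 13 at 85140001 to 85160000 (820 kb) and chromosome 5 at 162100001 to 162120000 (680 kb). The rule ranks by distance, so it favours places where the other list has few boundaries, such as the long stretches on chromosomes 16 and 7. No gene is assigned to these positions, because no hg18 annotation was used here.

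The third comparison asked how the segments between neighbouring boundaries changed. The ICI list defined 4932 segments, measured from window midpoint to window midpoint. Of these, 4399 (89.2%, 95% exact binomial interval 88.3 to 90.0%) had an E2 segment with a reciprocal overlap of at least 0.75. The rotations gave a mean of 9.13% and a highest value of 15.3% (one-sided permutation p over rotations = 0.001, the smallest possible). In the other direction, 4399 of 4923 E2 segments (89.4%) were stable. Among the segments that were not stable, 124 ICI segments (2.51%) were divided into 2 or more segments in estrogen-treated cells, and 131 E2 segments (2.66%) joined 2 or more ICI segments. Another 314 ICI segments (6.37%) lay together with other ICI segments inside 1 E2 segment, which could itself be stable, 94 (1.91%) were rearranged in other ways and 1 had no E2 segment over it. The counts of segments that were not stable were sensitive to the overlap required. Divided ICI segments numbered 11 at 0.5 and 146 at 0.9, and rearranged ICI segments 2 and 585. E2 segments that joined ICI segments numbered 4 and 158.

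Among segments that were not stable, the longest ICI segments that were divided in E2 lay on chromosomes 16, 6, 1 and 13. The 12.4 Mb stretch on chromosome 7 named above is not among them, because one of its parts, of 10.76 Mb in E2, makes it stable. The segment on chromosome 16 from 13910001 to 19470000 (5560 kb) was divided at 17.49 Mb. On chromosome 6, the segment from 76650001 to 79670000 (3020 kb) was divided at 78.25 Mb, and the segment from 95050001 to 97090000 (2040 kb) at 96.57 Mb. On chromosome 1, the segment from 28830001 to 30970000 (2140 kb) was divided at 30.37 Mb. The segment on chromosome 13 from 84330001 to 86310000 (1980 kb) held E2 boundaries at 85.15 and 86.21 Mb. Under the same limit, the longest E2 segments that joined ICI segments lay on chromosome 2 from 151070001 to 153310000 (2240 kb, without the ICI boundary at 152.67 Mb) and chromosome 5 from 90810001 to 92950000 (2140 kb, without that at 92.23 Mb). Those on chromosome 4 from 58810001 to 60790000 (1980 kb), chromosome 14 from 83750001 to 85630000 (1880 kb) and chromosome 18 from 49190001 to 50990000 (1800 kb) lacked the ICI boundaries at 59.99, 84.69 and 49.81 Mb.

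**Figure D2:**
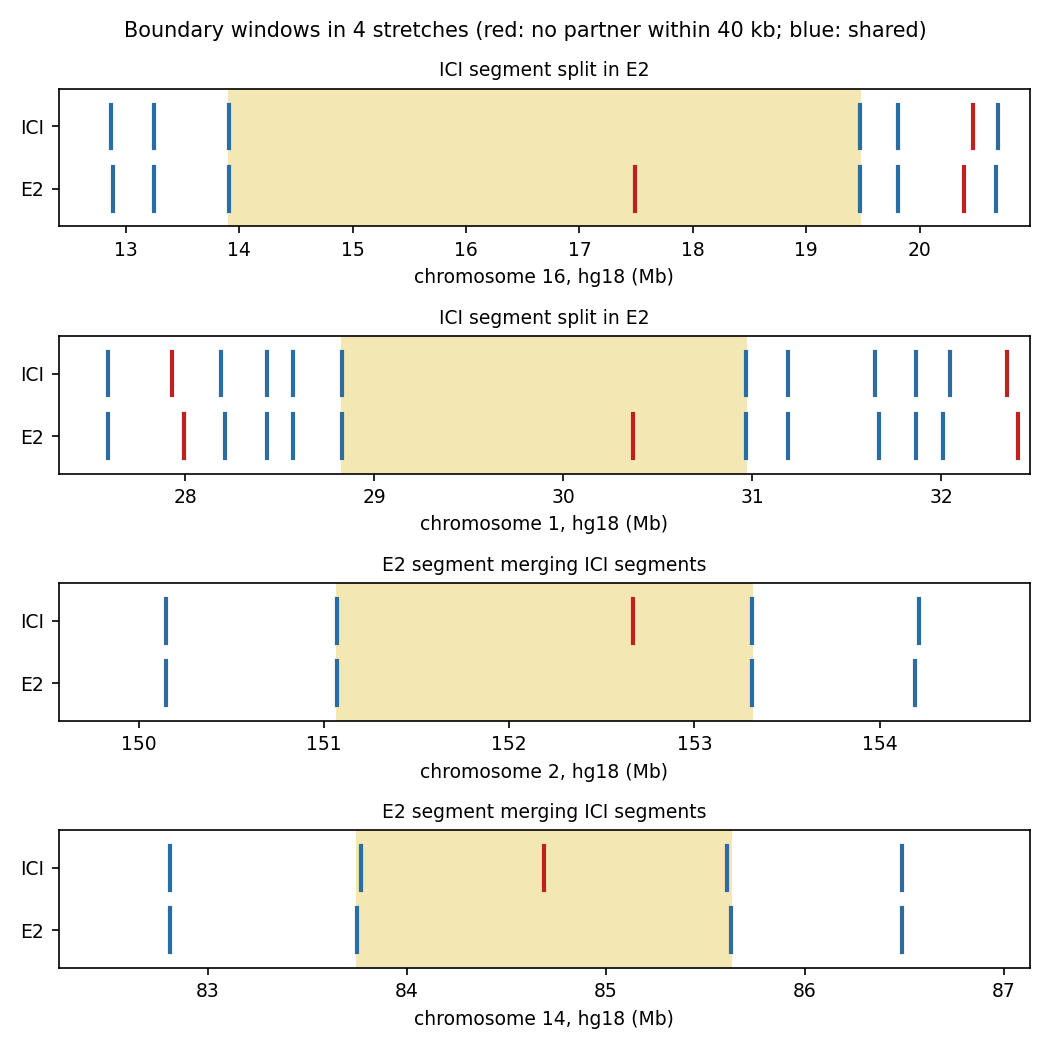
Boundary windows of the ICI list (upper row of each panel) and the E2 list (lower row) along 4 of the named stretches, with hg18 position in Mb on the horizontal axis; blue marks have a partner within 40 kb in the other list, red marks have none, and shading covers the named segment. The chromosome 16 and chromosome 1 segments gain an inner E2 boundary at 17.49 and 30.37 Mb, and the chromosome 2 and chromosome 14 segments lack the ICI boundary at 152.67 and 84.69 Mb.

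The shared percentage was lowest on chromosome X. On X, 186 of 215 ICI boundaries (86.5%, 95% exact binomial interval 81.2 to 90.8%) had an E2 partner within 40 kb, against 4400 of 4740 on the autosomes (92.8%, 92.1 to 93.5%). The single autosomes ranged from 87.7% on chromosome 9 to 96.5% on chromosome 14. When each chromosome was set against the others with Fisher's exact test (two-sided, Benjamini-Hochberg over 23 chromosomes), only X passed, at an adjusted p of 0.031, and chromosome 9 came next at 0.15. A shuffle of the partner status over all boundaries gave a permutation p = 0.065 for any difference among chromosomes, which missed the 0.05 threshold. For identical windows the chromosomes differed more (permutation p = 0.0001, the smallest that 10000 shuffles can give). The identical share was 81.1% on chromosome 20 and 78.1% on chromosome 17, against 58.6% on chromosome 9 and 57.7% on X. Fisher's exact test against the other chromosomes gave adjusted p-values of 0.026 for chromosome 20, 0.051 for 17, 0.026 for 9 and 0.022 for X. These tests on chromosomes were chosen after the values were seen.

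Chromosomes 2, 6, 11 and 21, which carry the genes named below, had shares from 92.7 to 94.2%, beside 92.6% over all chromosomes. The fixed list of estrogen-induced genes, which does not include ESR1, has members on further chromosomes, such as PDZK1 on chromosome 1 (91.2%). This range therefore does not stand for estrogen-induced genes in general. On chromosome 21, which carries TFF1 (a secreted trefoil peptide) and NRIP1 (a nuclear receptor corepressor), 65 of 70 ICI boundaries (92.9%) were shared, with 5 boundaries only in ICI and 5 only in E2. Chromosome 2, which carries GREB1, had 92.8% shared, and chromosome 6, which carries FOXC1 and the estrogen receptor gene ESR1, had 94.2%. Chromosome 11, which carries the progesterone receptor gene PGR and the cyclin gene CCND1, had 92.7%, with 18 ICI-only and 23 E2-only boundaries. None of chromosomes 2, 6, 11 and 21 passed Fisher's exact test against the others (adjusted p of 0.94 for chromosome 6 and 1 for the rest). These are values of whole chromosomes, and the boundaries nearest to the genes were not analysed here.

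**Figure D3:**
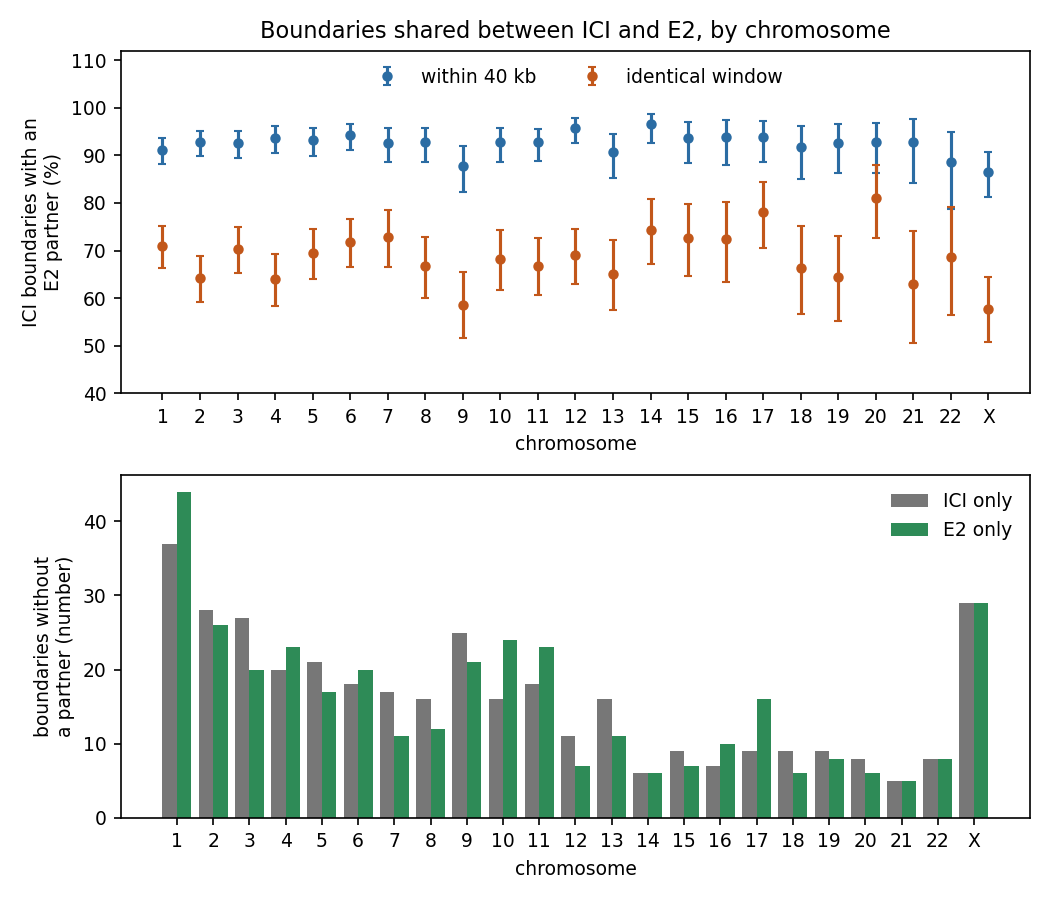
Upper panel, percentage of ICI boundaries with an E2 partner on each chromosome within 40 kb (blue) or at the identical window (orange), with 95% exact binomial intervals; the vertical axis starts at 40%. Lower panel, number of boundaries listed only in ICI (grey) or only in E2 (green) on each chromosome; X has 29 of each, and its blue point, at 86.5%, is the lowest of the 23.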

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

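The median spacings, the shared percentages, the counts of stable segments and the difference between autosomes and X kept their direction and their side of the threshold, or stayed within 1.5 times, under the alternatives that were run. In all, 63 alternative values did so and 14 did not. The alternatives that were not planned are all among the 63. The 63 include the counts of boundaries, whose alternatives only leave out a chromosome (4533 to 4885 in ICI against 4955) and so could not have moved by that much. They also include the shared percentages set against random positions, which change the comparison but cannot change the percentage. Leaving out X, with 215 of the 4955 ICI boundaries, could hardly move a shared percentage or a count of stable segments by that much. The same holds for the ICI median without the 45 of 4932 spacings that are over 3 Mb. Leaving out segments under 100 kb removes only those of 80 kb, the smallest spacing. The count of 63 is therefore no measure of robustness. The shared percentage of ICI boundaries was 68.3% at a tolerance of 0 kb, 87.6% at 20 kb, 95.1% at 80 kb and 92.8% on autosomes alone. The difference between autosomes and X was 11.1, 9.41 and 5.53 percentage points at 0, 20 and 80 kb against 6.32 at 40 kb. The number of boundaries without a partner followed the tolerance. At 0, 20 and 80 kb it was 1572, 614 and 245 in ICI against 369, and 1563, 605 and 236 in E2 against 360. At a minimum overlap of 0.5, the divided segments were 11 in ICI and 4 in E2, the segments lying with others inside 1 segment of the other list 191 and 192, and the rearranged ones 2 and 3. At 0.9, the rearranged ones were 585 and 590. By construction a looser overlap calls more segments stable, 4727 in ICI at 0.5 against 3874 at 0.9, and with identical ends required the shared ICI segments fell to 45.7% from 89.2%. No paired analysis was possible because each list holds both replicates of a condition, and for the same reason no replicate was left out. Leaving out the lowest scores was not run, since the lists hold no score, and the gene list alternatives were not run without an hg18 annotation. Read depth, which limits how precisely a boundary is placed, is unknown here.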

Other observations

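Most long stretches without a boundary were the same in both lists. In ICI, 45 stretches of over 3 Mb covered 313.76 Mb, 11.1% of the span between the outermost boundaries, and E2 also had 45, covering 310.64 Mb. Random positions of the same number gave a mean of 14.05 such stretches and at most 30 for the ICI list. These positions were drawn over the whole span, including centromeres, where the lists hold long gaps. The excess over random positions therefore does not show that the stretches are a feature of chromatin. Of the 45 ICI stretches, 35 had the same ends in E2 within 40 kb and no E2 boundary farther inside. Another 6 held an E2 boundary more than 40 kb inside their ends. The longest lay on chromosome 9 from 38.25 to 70.83 Mb and on chromosome 1 from 119.93 to 149.25 Mb, chromosomes with large heterochromatic blocks next to the centromere. Others lay away from centromeres, on chromosome 3 from 45.01 to 53.91 Mb, chromosome 12 from 6.29 to 12.11 Mb and chromosome 6 from 155.23 to 161.73 Mb. The first listed window of chromosome 1 had its start at 5.96 Mb in both lists, and that of chromosome 11 had its start at 5.04 Mb in ICI and 5.06 Mb in E2. These stretches were picked out after the data were seen, and no explanation was tested.

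The tests below on the estrogen treatment, on close neighbours, on gain against loss by chromosome and on arm differences averaged within chromosomes were chosen after the values they concern had been seen. Many of the boundaries without a partner had a near counterpart. Of the 369 ICI-only boundaries, 141 (38.2%) had an E2-only boundary within 100 kb, against a mean of 7.15 and at most 16 in 1000 random placements of the E2-only boundaries. This shows only that such pairs lay closer than random placement puts them. A candidate explanation is that the same boundary was placed slightly more than 40 kb apart in the lists, but a shift of the boundary under estrogen would give the same pairs, and with 1 list per condition these cannot be told apart. For the other 228 ICI-only boundaries, calls close to the threshold of the caller and an effect of estrogen stay open, both untested because the lists hold no score and no separate replicates.

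The lower sharing on chromosome X (86.5% against 92.8%) may have several sources. Wider spacing of boundaries on X is argued against as the whole source: in strata of local spacing set at its quartiles the autosome minus X difference was 6.62 percentage points (95% interval 2.00 to 11.2), close to the unadjusted 6.32. The difference was uneven, at 5.39, 6.08, 14.5 and 1.34 points from the closest to the widest spacing, with 30, 50, 58 and 75 boundaries on X. Copy number, which sets local read depth, was tested on the long arms of chromosomes 1, 17 and 20, taken beforehand as gained in MCF-7. They shared 1.39 percentage points more than the short arms (one-sided permutation p = 0.39), and 0.91 points more when averaged within chromosomes (95% interval -3.32 to 5.15), which does not settle it. Chromosome 17 went the other way, with 93.5% shared on the long and 94.7% on the short arm. Copy number in these cells is not known here, nor is which parts of these arms were gained. An effect of estrogen cannot be told apart from noise between libraries, since there is 1 list per condition. The equal 29 ICI-only and 29 E2-only boundaries on X carry no information on this. Both lists held 215 boundaries there, of which 186 were shared.

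The same arm comparison bears on the identical windows, which were more frequent on chromosomes 17 and 20 and less frequent on 9 and X. On chromosomes 1, 17 and 20 together, 77.2% of boundaries on the long arms and 70.3% on the short arms were at the identical window, a difference of 6.91 percentage points. Chromosome 1, whose identical share is lower, makes up more of the short-arm than of the long-arm boundaries, and averaged within chromosomes the difference was 5.42 points (95% interval -1.24 to 12.1). With arm labels shuffled within chromosomes the one-sided permutation p was 0.070, so copy number as a source could be neither excluded nor shown. Chromosome 17 alone went the other way, with 81 of 108 boundaries on the long and 33 of 38 on the short arm.

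Boundaries without a partner were not shown to gather in a few regions. The densest 5 Mb window held 9 of them, on chromosome 3 from 21.55 to 23.97 Mb, where 5 of 6 ICI and 4 of 5 E2 boundaries lacked a partner. Shuffling the status within chromosomes gave a median of 7.5 for the densest window, at most 12, and a permutation p = 0.13. Whether gain and loss differ between chromosomes was not settled. The chi-square of ICI-only against E2-only counts was 12.26 and the shuffle median 21.3, but the shared counts of the lists were equal on each chromosome, which ties ICI-only and E2-only counts to the list totals, and a shuffle of labels ignores this.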
